A study of Oxytricha trifallax with 2 samples.

How the data were processed

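Chromatin immunoprecipitation followed by paired-end sequencing was available for 2 libraries of the ciliate Oxytricha trifallax. Cells of the strains JRB310 and JRB510 had been mixed, each making up an equal part of a culture at 5000 cells per ml, and were taken 12 hr after mixing. One library was titled as the input chromatin and the other as the chromatin precipitated with an antibody to Rpb1, the largest subunit of RNA polymerase II. The groups were taken from these titles. The antibody field of the labels read the other way round, naming the Rpb1 antibody for the input and none for the ChIP library, so every direction given here rests on the titles and on the column names of the deposited tables. Each group had 1 library.

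The deposited tables give whole-number read counts per contig for both libraries, together with the contig length. Per the file headers, the authors divided the input reads of each contig by 1 normalization factor, 7.84, to make a normalized input signal, and subtracted it from the Rpb1 ChIP reads to make a corrected read score that can be negative. Both steps were recomputed on every contig and differed from the deposited values by at most 5e-05 reads. How the factor was obtained, the aligner, the genome build, the treatment of reads that match several contigs and any filter on reads are not given in the sources used here. One table held 22450 contigs. The other held 15993 contigs named for having 2 telomeres, all of them in the first table with the same counts, and with lengths that were 23 to 124 bp greater (median 51 bp). Lengths from the first table were used.

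The read counts summed to 12733402 for the Rpb1 ChIP library and to 2755534 for the input. Reads may be counted on more than 1 contig, so these totals are upper limits to the number of separate reads. From the counts, log2 of (ChIP reads + 1) over (input reads + 1) was computed per contig and centred on the median contig. Contigs with more than 8 input reads, the 5th percentile of contigs with any, were kept. Exact Clopper-Pearson 95% intervals of the ChIP share of a contig's reads were turned into intervals of the ratio, without the added read. They cover counting error only, because no molecular identifiers are recorded and no library was replicated. They were not adjusted for the choice of extremes among many contigs. With 1 library per group no test of the conditions was possible, no p-value for the ChIP against input difference was computed, and a fixed difference of 1 on the log2 scale was used to count contigs. Where a contig had no ChIP read, the upper bound of this interval set the limit.

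The contigs listed with 2 telomeres were compared with the remainder by the difference of medians, set beside 10000 random reassignments of that status within 10 groups of equal mean read level; its place among them describes these 2 libraries only. Spearman's rho across contigs described the relation to length. Contigs were named by a rule fixed before the data were examined: the 10 highest and 10 lowest centred ratios among contigs of at least 500 bp. Gene lists had also been fixed, but the gene table at hand covers the micronuclear assembly and shares no names with the contigs, so gene names, gene lists and GC content were not analysed here. Values along a contig were not analysed here either, since the tables hold 1 value per contig.

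The calculation was tested on simulated data, with Poisson counts drawn for the 20910 contigs of the ChIP against input comparison from their own input levels and 200 contigs changed. Of the contigs changed 4-fold upward, 100% passed a difference of 1, and of those changed to 0.25 of the ratio 98.1% did. For contigs changed 2-fold, exactly at the limit, the shares were 42.6% upward and 50% downward. Among unchanged contigs, which were all given 1 common ratio with no spread beyond counting, 0.295% passed it in either direction. The real ratios spread more widely than counting error, with an SD of 0.47 against 0.13 on well-covered contigs with 2 telomeres. The simulated share is therefore not an error rate for the contigs counted below. Other pseudocounts, filters, scalings and contig sets were tried as alternatives. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.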

Results

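Rpb1 occupancy was measured over the contigs of the macronuclear genome of Oxytricha trifallax, a ciliate whose somatic nucleus holds very many short chromosomes, called nanochromosomes, that typically carry a single gene between telomeres. Cells were sampled 12 hr after mating strains were mixed, during conjugation. The 2 libraries, 1 input and 1 Rpb1 ChIP, assigned 2755534 and 12733402 reads to 22450 contigs. The median contig was 2370 bp long and held 350 ChIP reads and 58 input reads. The middle 90% of contigs ran from 47 to 1259 ChIP reads and from 6 to 259 input reads. Reads were absent from both libraries on 125 contigs. There were no biological or technical replicates, so the intervals below cover counting error only and the differences are between these libraries. The antibody field of the sample labels contradicts the sample titles, and the directions follow the titles.

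The first comparison asked on which contigs Rpb1 was over- or under-represented relative to input DNA. Most contigs lay close to a common ratio. Among the 20910 contigs with more than 8 input reads, the median contig had 5.71 ChIP reads per input read, and the middle 90% of contigs spanned a 3.39-fold range, from -0.86 to 0.90 on the centred log2 scale. A ratio at least 2-fold above the median was found on 725 contigs (3.47%) and a ratio at least 2-fold below it on 557 (2.66%). When the 2 libraries were scaled by their totals instead, the median contig lay 0.31 higher on the log2 scale and the counts became 2104 higher and 127 lower. The 95% counting interval lay wholly beyond 2-fold for 78 of the higher contigs and for 152 of the lower ones. The higher contigs had a median of 24 input reads and the lower ones a median of 166. Of the 6725 contigs with at least 100 input reads, 45 were higher and 364 lower at this centre. Their own median lay at -0.29, and centred on it 172 were higher and 83 lower, so the order depends on the centre. With at least 100 input reads, on 5494 contigs with 2 telomeres, the ratio had an SD across contigs of 0.47 on the log2 scale, against 0.13 from counting error.

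**Figure D1:**
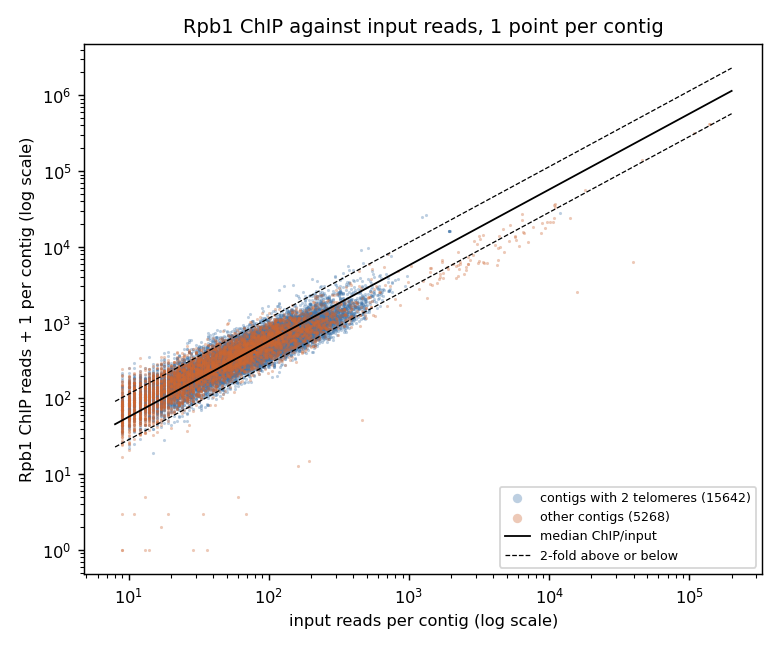
Rpb1 ChIP reads (plus 1, log scale) against input reads (log scale) for 20910 contigs, coloured by whether the contig is listed with 2 telomeres. The solid line is the median ratio of 5.71 ChIP reads per input read and the dashed lines lie 2-fold from it; a few contigs without that listing fall far below.

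The 10 contigs with the highest ratio stood 3.73-fold to 4.58-fold above the median contig. Of these, 7 are listed with 2 telomeres, as are 15642 of all 20910 contigs compared. Contig8764.0.1, of 2115 bp, was the highest, with 339 ChIP reads against 12 input reads and a centred log2 ratio of 2.19 (95% counting interval 1.48 to 3.27). Contig2171.0, of 1735 bp, had 295 ChIP reads against 11 and a centred log2 ratio of 2.11 (1.37 to 3.25). Contig703.0, Contig11850.0, Contig8654.0, Contig9578.0 and Contig8822.0 followed with 9 to 14 input reads each and centred log2 ratios of 1.92 to 2.08. Ratios of contigs picked as extremes with so few input reads may be overstated, and the intervals do not allow for this choice.

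The other three of these contigs rested on more reads and had similar lengths. Contig13258.0 (5333 bp) held 3009 ChIP reads and 128 input reads, for a centred log2 ratio of 2.03 (1.79 to 2.31). Contig12287.0 (5344 bp) held 2678 and 118 reads, for 1.98 (1.72 to 2.27), and Contig15068.0 (5397 bp) held 3176 and 148 reads, for 1.90 (1.67 to 2.16). Whether reads were shared between them is not known. With at least 100 input reads, a limit chosen after the values were seen, the next in order were Contig4220.0 at 1.80 (1.72 to 1.89), Contig10038.0 at 1.79 (1.66 to 1.94) and Contig7757.0 at 1.79 (1.71 to 1.87). Their lengths were similar too (1398, 1356 and 1387 bp), and whether reads were shared between them is likewise not known. All contigs named in this paragraph are listed with 2 telomeres, as are 5494 of the 6725 contigs with at least 100 input reads.

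At the low end, the 10 contigs with the lowest ratio held 0 to 14 ChIP reads against 9 to 194 input reads, and none is listed with 2 telomeres. Contig6709.0 (1139 bp) had 0 ChIP reads against 36 input reads, at least 52.9-fold lower than the median contig by the upper bound of its 95% counting interval. Contig565.0 (960 bp) had 0 against 29, at least 42.1-fold lower. Contig8035.0, Contig8521.0 and Contig3997.0 also had 0 ChIP reads, against 14, 13 and 9 input reads, which gives at least 18.9-fold, 17.4-fold and 11.3-fold lower ratios by the same bound. Contig4212.0 held 2 ChIP reads and 69 input reads, with a centred log2 ratio of -7.06 (-10.70 to -5.72), and Contig8393.0 held 2 and 34, with -6.06 (-9.70 to -4.64). Contig7763.0.0 (1540 bp) had 14 against 194, with -6.21 (-7.20 to -5.53). Contig6077.0 (1982 bp) had 12 against 162, with -6.16 (-7.25 to -5.42), and Contig7118.0 (695 bp) had 4 against 60, with -6.12 (-8.34 to -4.99).

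**Figure D2:**
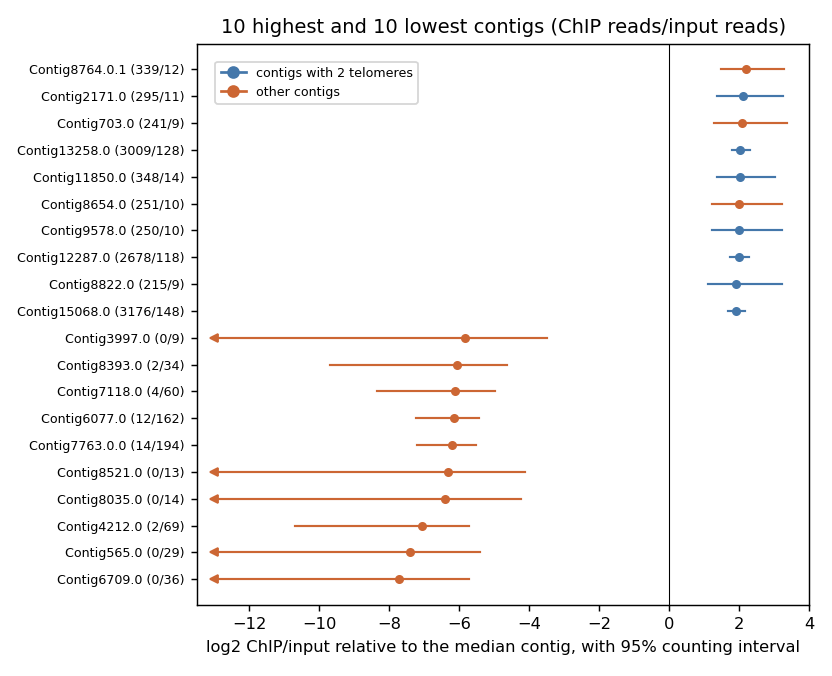
Centred log2 ratio of Rpb1 ChIP to input reads for the 10 highest and 10 lowest contigs of at least 500 bp, with ChIP and input reads in brackets; lines are 95% counting intervals and arrowheads mark intervals open below because no ChIP read was counted. The lowest 10 lie at -5.84 or less, all outside the 2-telomere listing.

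The second comparison set the contigs listed with 2 telomeres, called complete nanochromosomes here, against the remainder. Their completeness was taken from that listing and was not checked. The complete nanochromosomes took 65.9% of the ChIP reads and 56.2% of the input reads (exact 95% binomial intervals 65.87% to 65.92% and 56.10% to 56.22%). Such intervals of read shares take each read as separate, although reads may be counted on several contigs, and leave out the spread between contigs. Among the others, the 4 contigs with the most ChIP reads, Contig6496.0, Contig2217.0, Contig8287.0 and Contig1610.0, together took 10.1% of the ChIP reads and 15.7% of the input reads. Without these 4 contigs the complete nanochromosomes took 73.3% of the ChIP reads and 66.6% of the input reads, so the order stayed. Without the 84 of the others that had at least 1000 input reads, a limit chosen after the values were seen, the shares were 79.4% of the ChIP reads and 80.4% of the input reads (79.42% to 79.47% and 80.38% to 80.49%), so the order turned. That exclusion went by input reads, the denominator of the ratio, and kept the 8 contigs with 2 telomeres and as many input reads. Per contig, the ratio was lower on the complete nanochromosomes. The median centred log2 ratio was -0.03 over 15642 contigs with 2 telomeres and 0.08 over 5268 others, a difference of -0.11. Random reassignment within groups of equal read level gave a mean of -0.03, and the observed difference was lower than each of the 10000 reassignments. When contigs were matched on length as well, reassignment gave a mean of -0.13 (95% range -0.15 to -0.12), and the observed difference then exceeded 99.1% of the reassignments, so its direction relative to matched contigs turned. Matching read level and length together also matches reads per kb, so the turn does not show an effect of length alone. By length class alone, the medians with 2 telomeres and of the others were -0.37 and -0.42 up to 1000 bp. They were -0.08 and 0.03 from 1000 to 2000 bp, and 0.004 and 0.15 from 2000 to 4000 bp. Longer classes had 0.03 and 0.15 up to 10000 bp, and 0.22 and 0.37 above. Past 1000 bp the ratio thus stayed lower with 2 telomeres.

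A ratio at least 2-fold above the median occurred on 494 of the contigs with 2 telomeres (3.16%) and on 231 of the others (4.38%). The higher share of the others was not seen where the counting interval had to lie wholly above 2-fold, with 62 (0.396%) and 16 (0.304%) contigs. These counts are too small to give an order. The others had fewer reads, with a median of 46 input reads against 70. A ratio at least 2-fold below the median occurred on 366 (2.34%) and on 191 (3.63%), and the interval lay wholly beyond 2-fold on 57 (0.364%) and 95 (1.80%). The interval counts also depend on read depth, which was not separated. The higher share of the others was seen on short contigs, with 8.75% and 16.8% up to 1000 bp and 2.51% and 4.32% from 1000 to 2000 bp. From 2000 to 4000 bp the order was the other way, with 2.19% and 1.74%. From 4000 to 10000 bp the shares were 1.12% and 1.16%. All 18 contigs with a centred log2 ratio of -4 or less, a 16-fold deficit, belonged to the others, as did Contig794.0, just above that limit.

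**Figure D3:**
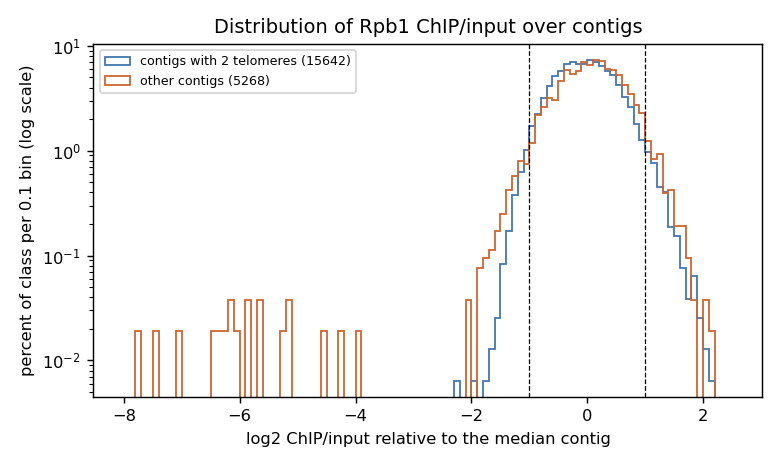
Distribution of the centred log2 ratio of Rpb1 ChIP to input over 15642 contigs with 2 telomeres and 5268 others, as percent of each class per bin of 0.1 (log scale), with dashed lines 2-fold from the median. The main bodies overlap, with medians of -0.03 and 0.08, and a separate tail of 19 contigs at about -4 and below holds only contigs outside the 2-telomere listing.

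The third comparison related the ratio to contig length. Short contigs had less Rpb1 ChIP per input read. The median centred log2 ratio was -0.38 over 1221 contigs of up to 1000 bp, -0.05 over 6298 contigs of 1000 to 2000 bp, 0.04 over 8518 of 2000 to 4000 bp, 0.05 over 4537 of 4000 to 10000 bp and 0.26 over 336 longer ones. Among contigs of up to 1000 bp, 11.5% lay at least 2-fold below the median and 0.328% at least 2-fold above it. Of the 336 contigs over 10000 bp, 0 lay 2-fold below and 3.27% lay 2-fold above. In the classes between, in order of length, 3.73%, 4.09% and 2.80% lay 2-fold above, so past 1000 bp that share did not rise with length. Spearman's rho across contigs, which are not independent replicates, was 0.13 over all contigs and 0.12 over those with 2 telomeres. It was 0.26 over contigs with more than 28 input reads and 0.02 over contigs of at least 1500 bp. A filter on input reads keeps short contigs only where their input per kb is high, and its effect was not separated from that of length.

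**Figure D4:**
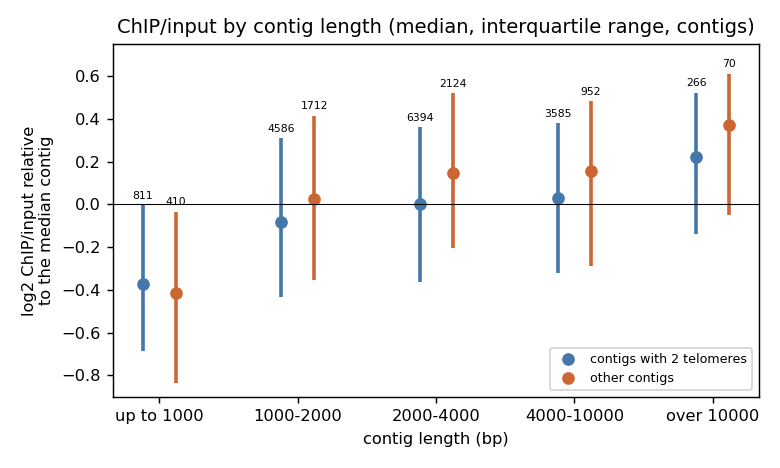
Centred log2 ratio of Rpb1 ChIP to input by contig length in bp, for contigs with 2 telomeres and for others; points are medians, bars are interquartile ranges and the numbers count contigs. The medians of the shortest class are -0.37 and -0.42, and those over 10000 bp are 0.22 and 0.37.

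The deposited corrected reads followed the ChIP reads almost exactly. The authors' normalized input amounted to 2.76% of all ChIP reads, and to 2.15% on the median contig, because the input, which is the shallower library, was divided by 7.84. The corrected reads had a Spearman rho of 0.9999 with the ChIP reads across all 22450 contigs. Across the 20910 contigs with more than 8 input reads, their rho was 0.84 with contig length and -0.001 with the ratio of ChIP to input. The corrected reads were negative on 41 contigs, of which 0 are listed with 2 telomeres. If the input were scaled up to the ChIP total instead, 6115 contigs (27.2%) would have fallen below 0. Of the 10 contigs with the most corrected reads, led by Contig6496.0 with 412612 ChIP reads and 140848 input reads, 0 were among the 10 with the highest ratio and 1 had a ratio at or above the median.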

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

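The alternatives were fixed before the data were examined, except scaling by library totals, the minimum of 100 input reads, 1 contig per set of equal counts, the filters and contig sets at the unchanged centre, the exclusion of contigs at -4 or less and the length minimum of 1500 bp. The interquartile range of the centred log2 ratio, 0.74, became 0.67 with a pseudocount of 10. With the input as the authors normalized it, the median log2 ratio was 5.48 in place of 2.51. The share of contigs at least 2-fold higher, 3.47%, was 2.16% with a pseudocount of 10, 99.8% without centring and 10.1% with scaling by totals. The share at least 2-fold lower, 2.66%, was 0.0909% without centring and 0.607% with scaling by totals. Without centring, both shares follow mainly from the greater depth of the ChIP library and do not bear on the spread between contigs. Filters and contig sets were centred anew on the contigs they kept, except that the 2-telomere set kept the centre. The 6725 contigs with at least 100 input reads have a median ratio of -0.29 at the main centre: centred anew, 2.56% were higher and 1.23% lower, and at the unchanged centre 0.669% and 5.41%, so the order of the shares depends on the centre. At the unchanged centre the filter of more than 28 input reads gave 1.89% higher. The other alternatives kept both shares within 1.5 times. The difference between contigs with 2 telomeres and others, -0.11, was -0.13 without a filter and -0.084 with more than 28 input reads. Beyond level-matched lists it was -0.078, and it turned to 0.021 when length was matched as well, which also matches reads per kb; the cause was not tested. The Spearman correlation with length across contigs, 0.13, was 0.12 for 2-telomere contigs, 0.26 with more than 28 input reads and 0.025 from 1500 bp. No replicate could be left out and no paired analysis was possible because each group had 1 library. Alternatives on gene lists, GC content and position along the contig were not run, for want of matching names, sequence and positions. By their counting interval, 78 of the 725 higher contigs (10.8%) and 152 of the 557 lower ones (27.3%) passed 2-fold. The higher contigs had fewer input reads, and depth was not separated from how near the ratios lay to the limit.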

Other observations

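Tests below on input density with separate parts of the input, on counting error and telomere status of the 19 contigs with the lowest ratios and on the contigs of about 66 kb were chosen after the result was seen.

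Among the complete nanochromosomes, 2 contigs of similar length carried the most Rpb1 ChIP reads per kb. Contig7757.0 (1387 bp) had 18917 ChIP reads per kb and Contig4220.0 (1398 bp) had 17596, which is 129-fold and 120-fold the median of 147 per kb over contigs with 2 telomeres. Their input was high as well, at 38.0-fold and 35.1-fold the median of 25.2 reads per kb. Whether reads were shared between these 2 contigs is not known. Contig20269.0, of only 248 bp, was next with 10992 ChIP reads per kb and a centred log2 ratio of 0.84. Contig10038.0 and Contig19738.0 followed with 6614 and 5199 ChIP reads per kb and centred log2 ratios of 1.79 and 1.73. Contig451.1 (7527 bp) held the most ChIP reads of any contig with 2 telomeres, 28074, but it had 11942 input reads, and its centred log2 ratio was -1.28 (95% counting interval -1.31 to -1.25).

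Contigs with more input reads per kb had less Rpb1 ChIP per input read. With the input reads split at random into 2 parts, 1 for the density and 1 for the ratio, Spearman's rho across contigs with 2 telomeres was -0.57 (-0.72 without the split), which argues against shared counting noise as the whole source. From the lowest to the highest decile of density in the first part, the input per kb in the second part rose 6.29-fold, the ChIP reads per kb 2.96-fold, and the median centred log2 ratio to the second part went from 0.42 to -0.60. Within 10 groups of equal length the median rho was -0.63 (-0.75 to -0.24), which argues against length. A trend with base composition or amplification in library preparation, and Rpb1 loading that does not scale with chromosome copy number, may each give such a pattern and remain untested, since no sequence or second library was used here.

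A separate set of 19 contigs lay far below the rest, 18 of them at a centred log2 ratio of -4.25 or less and Contig794.0, with 4 ChIP reads and 13 input reads, just above -4 (95% counting interval -6.29 to -2.52); the next lowest value was -2.27. If every contig had the ratio of the 1st percentile, binomial counting would be expected to put 0.000735 contigs at -4 or less and 0.0251 at -3 or less, which argues against counting error of few reads. None of the 19 (0) is among the contigs with 2 telomeres, as DNA that is not macronuclear Oxytricha chromatin, such as organelle DNA or DNA of food organisms, would need, but fragments of incomplete contigs would be outside that list too, so this source cannot be told apart without a sequence match. The 18 contigs at -4.25 or less held 2.05% of the input reads and 0.0700% of the ChIP reads, almost all on Contig228.0.0 and Contig228.0.1, with 8820 ChIP reads against 55205 input reads, or 0.160 per input read, while the other 16 contigs had 92 against 1149, or 0.0801.

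As a check for reads assigned to several contigs, equal pairs of counts were sought in both libraries: among 20351 contigs with more than 50 ChIP reads and more than 10 input reads, 6116 shared their exact pair of counts with another contig. Redrawing the counts at each contig's own level gave a median of 5532 such contigs and at most 5700, so chance ties could account for most of them. Lengths within the sets differed by a median of 562 bp, 0.720 of the 781 bp between neighbours in ChIP count, which speaks against the same reads on similar contigs as the source of most of these ties. The ties seen were still more than in any redraw, and a median over all sets cannot show the source of that excess. Shared reads also need not give exactly equal counts. The 5 contigs of 65938 to 65982 bp, in contrast, held 16267 to 16323 ChIP reads and 1937 to 1956 input reads, and the variance of these counts over their mean was 0.0330 and 0.0262, where separately sampled reads would give about 1. Reads counted on, or divided over, each of these similar contigs may explain this, and their centred log2 ratios of 0.54 to 0.56 then amount to a single measurement.

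Of the contigs without the 2-telomere listing, 84 had at least 1000 input reads, and they took 30.2% of the input reads and 17.1% of the ChIP reads. The 2-telomere contigs took 65.9% of the ChIP reads against 56.2% of the input reads, and 79.4% against 80.4% without these 84. The 84 were picked by input reads, the denominator of the ratio, and from the others only, so the change gives no cause. All 84 lay below the median ratio, with a median centred log2 ratio of -1.25 (interquartile range -1.47 to -0.91). Of the 8 contigs with 2 telomeres and as many input reads, 5 of them the contigs of about 66 kb, 1 lay below it, and their median was 0.55.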
